A study of Mus musculus with 6 samples.

How the data were processed

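RNA sequencing libraries were analysed from subcutaneous CT26 tumours, a murine colorectal carcinoma line grown in female BALB/c mice. There were 3 libraries from mice given vehicle and 3 from mice given TP-18, a compound known here only by its code name. Groups and replicate numbers were taken from the sample labels. The labels disagree on the sorted cells: the series design names flow-sorted CD11b+F4/80+CD206+ macrophages, the treatment protocol names CD11b+ selection on magnetic beads, and the sample characteristics name the CT26 line itself. Libraries were made with the VAHTS Universal V6 kit, per the labels' protocols, and whether strand was kept or used in counting was not given in the sources used here. The labels do not say that each library came from a separate mouse, so p-values measure the spread between these samples, which may be partly technical.

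The authors deposited raw counts per gene for 17191 genes and, in a second table, FPKM values. Per the submitters' processing notes, fastp, HISAT2 and HTSeq were used with the GRCm38 build, and no versions or settings are listed there. The annotation release was not given in the sources used here. The deposited FPKM values equal count divided by the library's total count and by 1 length per gene, checked on every gene. Both tables carry Entrez identifiers and GO and KEGG terms per gene. Chromosome positions were taken from GENCODE M21 on GRCm38 through the Entrez identifier for 16599 genes and the symbol for 247. The remaining 345 genes had no match.

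Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr defaults (a minimum count of 10 and a minimum total of 15), which left 12721 genes, and libraries were scaled with TMM factors. The quasi-likelihood test compared TP-18 with vehicle without covariates, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. CPM values use the TMM-scaled library sizes. Standard errors were computed as the absolute log2 fold change divided by the square root of the F statistic. Total counts ran from 16371128 to 17597645 per library. Between libraries of a group, log2 CPM values correlated across genes at 0.952 to 0.978 and the counts differed by more than sampling noise, so no library was treated as a copy of another. Between the groups the correlations were similar, at 0.941 to 0.974. Vehicle 1 correlated more with TP-18 3 (0.974) and TP-18 1 (0.971) than with vehicle 2 (0.952) or vehicle 3 (0.961).

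Before the data were examined, 35 gene lists were fixed, 22 of programs and 13 of cell type markers, together with the test, the alternatives and the rule for naming genes. They were tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, two-sided, over the 33 lists with at least 5 tested members, and again with an estimated correlation and with fry. GO and KEGG terms with 15 to 300 tested genes were tested in the same way. Camera with an estimated correlation also uses only the few residual degrees of freedom of the 6 libraries. Its p-values can therefore rise even where the estimated correlation is low, and a call lost with it need not reflect correlated members. Named genes were up to 12 per direction past the threshold with a mean CPM of at least 1 and groups that do not overlap; where fewer than 5 passed in a direction, the 10 with the smallest p in it. From each program list the rule took up to 4 members past the threshold, or up to 2 of the most abundant, and from each marker list up to 2 of the most abundant. For lists that did not pass only some of these are given, chosen after their values were seen. Itgam, Adgre1, Mrc1, Arg1, Nos2, Ptger4, Ptger2, Cd274 and Il10 were named always. Members that passed only when adjusted over the list alone, and any other gene outside this rule, were chosen for naming after their values were seen.

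The test was run first on simulated counts for TP-18 against vehicle, drawn from the real means and library sizes with known changes in a fixed set of genes. Among 12569 genes it recovered 1 of 67 genes changed 1.5-fold, 23 of 67 changed 2-fold and 57 of 66 changed 4-fold. Of 89 calls, 8 were unchanged genes. Alternatives were RLE factors or library totals as scaling, DESeq2 1.42.0, limma-voom with and without sample weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other filters, a replicate block, fold thresholds including glmTreat at 1.2-fold, and each library left out in turn. Chosen after seeing the data were a correction for GC content and transcript length (mgcv 1.9.3) and a fit with 1 surrogate variable (sva 3.50.0). Medians of the fixed lists were also computed under each scaling. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.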

Results

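Messenger RNA was profiled in cells taken from subcutaneous CT26 tumours of female BALB/c mice aged 6 to 8 weeks. Mice entered treatment once tumours measured 100 to 200 mm3 and received vehicle or TP-18 by mouth at 50 mg/kg once daily for 3 weeks. There were 3 libraries per group, with total counts of 16371128 to 17597645 and 14690 to 15424 genes with a count. TMM factors ran from 0.924 to 0.962 in the vehicle libraries and from 1.05 to 1.07 in the TP-18 libraries. The sort markers were abundant in both groups. Itgam, which encodes CD11b, had 1012 ± 272 CPM in vehicle and 889.8 ± 112 CPM in TP-18 libraries (SD, n = 3 each). Mrc1, which encodes CD206, had 977 ± 412 and 776 ± 136 CPM, and Adgre1, which encodes F4/80, had 192 ± 98.0 and 191 ± 75.7 CPM. None of these 3 genes passed the edgeR test.

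The comparison asked how the transcriptome of these tumour-derived cells differed after TP-18. In the TP-18 libraries 11 genes fell and 3 rose among 12721 tested. Those that fell included the cytokines Csf1, the growth factor of macrophages, and Lif, a member of the interleukin-6 family, the signalling adaptor Traf1 and the chaperone Hspa1b. Those that rose included the matrix genes Col6a3 and Fbn1. As groups, NF-kB targets, immediate early and heat shock genes and unfolded protein response genes were lower, and cell cycle genes and markers of fibroblasts, endothelial cells and mast cells were higher, in tests that used a preset correlation between genes. Of the 33 tested lists, 14 passed in this way, and 0 passed with an estimated correlation (smallest adjusted p = 0.323) or with fry's directional test (smallest adjusted p = 0.0552). The mixed test of fry, which takes changes in either direction together and so gives no direction, passed 6 (smallest adjusted p = 0.00228).

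Csf1 fell from 516 ± 47.6 to 164 ± 35.6 CPM (SD, n = 3 each), a log2 fold change of -1.65 ± 0.19 (SE) with an edgeR adjusted p = 0.0428. Sox9, a transcription factor, fell from 149.8 ± 16.2 to 44.9 ± 3.07 CPM, a log2 fold change of -1.74 ± 0.14 with an edgeR adjusted p = 0.0137. Lif fell by 1.71 ± 0.18 and Traf1 by 1.70 ± 0.18 on the log2 scale, with edgeR adjusted p = 0.0416 and 0.0420. Hspa1b, an inducible chaperone, fell by 1.57 ± 0.19 from 947 ± 134 CPM, and its count is uncertain because the neighbouring Hspa1a is nearly identical. The other genes that fell were Sema4b, a semaphorin (-1.52), Dusp5, a phosphatase of ERK kinases (-1.49), Stx11, a syntaxin (-1.35), the co-chaperone Dnajb2 (-1.22), the transcription factor Ets1 (-1.09) and the circadian gene Noct (-1.08). Iqcn rose from 3.26 ± 0.985 to 30.1 ± 1.48 CPM, a log2 fold change of 3.20 ± 0.25 with an edgeR adjusted p = 0.0137. Col6a3, a collagen VI chain, rose by 1.96 ± 0.21 on the log2 scale to 57.7 ± 14.2 CPM. Fbn1, which encodes fibrillin, rose by 1.39 ± 0.16 to 24.1 ± 1.64 CPM. Each of the 14 genes had every TP-18 library beyond every vehicle library.

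**Figure D1:**
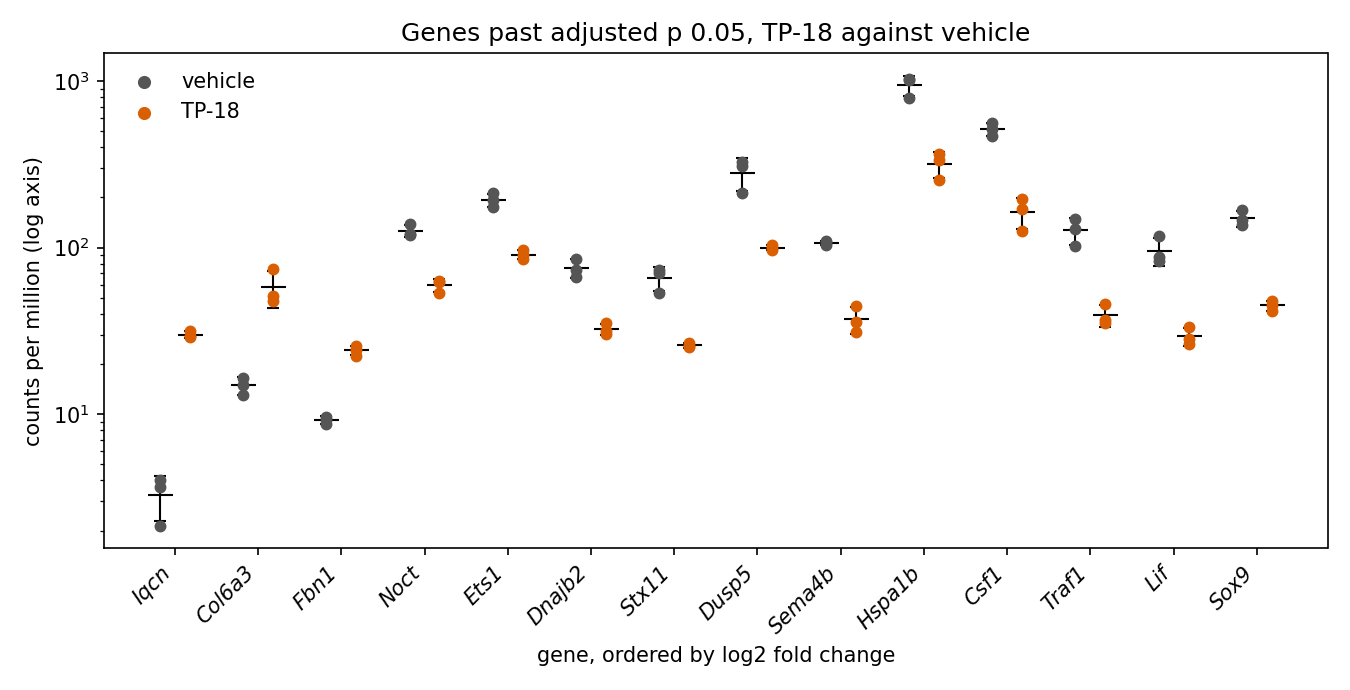
CPM on a log axis for the 14 genes past adjusted p 0.05 in edgeR's quasi-likelihood test, one point per library, with black bars for the mean and SD of 3 libraries. Grey vehicle points and orange TP-18 points do not overlap for any of the genes, and Csf1 lies at 516 CPM in vehicle and 164 CPM in TP-18 libraries.

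On GRCm38, all 14 genes are annotated as protein-coding. Csf1 (Entrez 12977) spans 107741048 to 107760469 on chromosome 3 and Lif (16878) spans 4257557 to 4272514 on chromosome 11. Sox9 (20682) spans 112782224 to 112787760 on chromosome 11, and Traf1 (22029) spans 34941750 to 34961772 on chromosome 2. Hspa1b (15511) is a gene of 1 exon at 34956436 to 34959238 on chromosome 17. Col6a3 (12835) lies at 90765923 to 90843971 on chromosome 1, Iqcn (637079) at 70703457 to 70717650 on chromosome 8. Fbn1 (14118), at 125300594 to 125507993 on chromosome 2, shares exonic sequence with Gm9913 on the opposite strand, and Dusp5 (240672), at 53529109 to 53542431 on chromosome 19, with AC137853.2. Since strand use is unknown, reads within the shared stretches cannot be told apart between Fbn1 or Dusp5 and those partners. The length of these stretches was not measured. Sema4b (20352) lies at 80186841 to 80226527 on chromosome 7, Stx11 (74732) at 12938209 to 12964298 on chromosome 10 and Dnajb2 (56812) at 75236406 to 75245692 on chromosome 1. Ets1 (23871) lies at 32636221 to 32757820 on chromosome 9 and Noct (12457) at 51224447 to 51251644 on chromosome 3.

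Next by p among genes with higher values were Trim69, Tnc, Col12a1, Keap1, Col5a2, Angptl2 and Kdr, none of which passed. Tnc, which encodes the matrix protein tenascin C, had 19.3 ± 9.04 CPM in vehicle and 103 ± 8.91 CPM in TP-18 libraries (edgeR adjusted p = 0.0666). Col12a1 had 14.3 ± 4.42 and 113 ± 61.2 CPM (edgeR adjusted p = 0.0668). Keap1, the repressor of the antioxidant regulator NRF2, had 38.2 ± 2.75 and 65.9 ± 1.45 CPM (edgeR adjusted p = 0.0788). At an unadjusted p under 0.05, 962 genes were higher and 1107 lower, where chance gives 636 in all. In 2966 genes (23.3%) the groups did not overlap, against the 10% that chance gives for 3 against 3. Without vehicle 1 edgeR called 3 genes higher and 5 lower, 6 of them among the 14, without vehicle 2 it called 1 and 0, that 1 among the 14, and without any 1 of vehicle 3, TP-18 1, TP-18 2 and TP-18 3 it called 0, with 1169 to 1855 genes at an unadjusted p under 0.05. With library totals as scaling, which shifted the median log2 fold change of all genes by 0.18, 3 genes were higher and 1 lower, and DESeq2 called 163 higher and 342 lower, the 14 genes among them. Only 2 of the 14 stayed called with a replicate block, with either limma fit on FPKM values or with glmTreat.

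The NF-kB target list, genes induced by the main inflammatory transcription factor, was lower in the TP-18 libraries (camera adjusted p = 4.83e-12). This became adjusted p = 0.388 with an estimated correlation. All 27 tested members had negative log2 fold changes, 25 with library totals as scaling, with a median of -0.82. Of these, 1 passed over all genes and 14 were lower when adjusted over the list alone, among them Nfkb1, Relb, Nfkbia, Tnfaip3, Tnf and Il6. Nfkbia, the inhibitor that NF-kB itself induces, had 1906 ± 221 CPM in vehicle and 1079 ± 100.5 CPM in TP-18 libraries. Tnf had 419 ± 116 and 178 ± 62.8 CPM and Il6 had 23.5 ± 13.0 and 5.23 ± 1.86 CPM. Markers of macrophages lay at a median of -0.27 in the same libraries and did not pass as a list, but this median was -0.53 without vehicle 2, where the list passed as lower, -0.04 without vehicle 3 and -0.09 with library totals.

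Immediate early and heat shock genes were also lower as a list (camera adjusted p = 3.30e-08). This became adjusted p = 0.323 with an estimated correlation. Of 27 members, 24 were negative, 1 passed over all genes, and 14 were lower and 1 higher when adjusted over the list alone. The 8 heat shock genes had a median log2 fold change of -1.17, with Hspa8 at 2872 ± 88.1 CPM in vehicle and 1650.02 ± 178 CPM in TP-18 libraries. Of the list's immediate early genes, a chosen set of 10 had a median of -0.15: Fos, Fosb, Jun, Junb, Egr1, Ier2, Atf3, Zfp36, Dusp1 and Btg2. In this set 7 were negative, against 8 of the 8 heat shock genes. Other members, such as Jund, Egr2, Egr3, Ier3, Klf2 and Myc, lie outside both sets, and their median was not computed. Egr1, the member that was higher over the list alone, had 1584 ± 87.3 and 2177 ± 231 CPM. The unfolded protein and integrated stress response list was lower (camera adjusted p = 0.000662). This became adjusted p = 0.323 with an estimated correlation. The estimate was -0.004, below the preset 0.01, so a higher correlation between members was not what ended this call. The list held 0 genes past the threshold over all genes, and 9 lower and 1 higher, Vldlr, when adjusted over the list alone. Hspa5, the main chaperone of the endoplasmic reticulum, had 4142 ± 361 and 2544 ± 220.4 CPM, and Hsp90b1 had 1153 ± 75.8 and 1077 ± 61.9 CPM.

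The list of classically activated macrophage genes was lower (camera adjusted p = 0.00197). It had an adjusted p = 0.388 with an estimated correlation, and 17 of 21 members were negative. Its members Tnf and Il6, both also on the NF-kB list, were lower when adjusted over the list alone, and 0 passed over all genes. Ptgs2, the inducible cyclooxygenase, had 1274 ± 151 and 914 ± 64.0 CPM, and Il1b had 431 ± 58.1 and 403 ± 148 CPM. Genes induced by cAMP and CREB were lower (camera adjusted p = 0.00106). They had an adjusted p = 0.388 with an estimated correlation, and 19 of 22 were negative. Crem was the 1 member lower when adjusted over the list alone, with 0 over all genes. Thbs1 had 1959 ± 1778 and 706 ± 719 CPM, and Dusp1 had 947 ± 106 and 638 ± 166 CPM. Thbs1 ranged from 328 CPM in vehicle 1 to 3854 CPM in vehicle 2 and is among the genes called in another split of the libraries, given below. Chemokine genes were lower with a median of -0.59 (camera adjusted p = 0.0343). They had an adjusted p = 0.422 with an estimated correlation, and 0 of 24 members passed over all genes or adjusted over the list alone, with Cxcl2 at 1604 ± 783 and 925 ± 292 CPM and Cxcl1 at 1277 ± 396 and 636 ± 114 CPM. The immunosuppressive list was lower (camera adjusted p = 0.0131). It had an adjusted p = 0.423 with an estimated correlation, and Il1rn, the interleukin-1 receptor antagonist, was the 1 member lower when adjusted over the list alone, against 0 over all genes. Many tested members are on another fixed list too: 13 of 21 classically activated, 10 of 22 cAMP, 8 of 24 chemokine and 8 of 20 immunosuppressive genes. Cxcl1 and Cxcl2 are also on the NF-kB list, so these calls rest partly on the same genes. The chemokine and immunosuppressive calls ended without vehicle 2, without vehicle 3 or without TP-18 1 (camera adjusted p = 0.0584 to 0.115), and with a GC and length trend removed (0.485 and 0.0658). With that trend removed the chemokine median went from -0.59 (95% bootstrap interval over members -0.99 to -0.13) to -0.41 (-0.81 to -0.05), while the immunosuppressive median was -0.22 (-0.49 to -0.01) and then -0.25 (-0.52 to 0.03). Without the correction but with library totals as scaling, which shifts all genes, the immunosuppressive median was -0.04 and the chemokine median -0.42, and those of the cAMP, classically activated and unfolded protein lists were -0.25, -0.29 and -0.10, against -0.43, -0.47 and -0.27 with TMM. Camera sets a list against all other genes, and the mean t over all genes fell from 0.116 to -0.203 with the trend removed, so that the immunosuppressive list stood out less. Lgals3 had 1281 ± 399 and 965 ± 211 CPM. Cd274, which encodes PD-L1, had 258 ± 103 and 140.5 ± 47.9 CPM, and Il10 had 41.1 ± 6.91 and 24.7 ± 5.54 CPM, and neither passed.

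The antioxidant and iron handling list was lower (camera adjusted p = 0.00696). It had an adjusted p = 0.388 with an estimated correlation, with Srxn1 and Fth1 lower when adjusted over the list alone and 0 over all genes. Fth1, the ferritin heavy chain, had 5280 ± 1075 CPM in vehicle and 3225 ± 239 CPM in TP-18 libraries, and Ftl1 had 4120 ± 889 and 2795 ± 135 CPM. The oxidative phosphorylation list was lower, with a median of -0.16 that became 0.01 with library totals as scaling (camera adjusted p = 0.00387). It had an adjusted p = 0.750 with an estimated correlation, and 0 of 31 members passed over all genes or adjusted over the list alone, with Atp5b at 1231 ± 129 and 1112 ± 99.3 CPM and Atp5a1 at 671 ± 44.5 and 622 ± 27.8 CPM. The oxidative phosphorylation call ended without vehicle 2 or TP-18 2 (camera adjusted p = 0.0754 and 0.0945), and with the trend on GC content and length removed it and the antioxidant call ended (0.7698 and 0.0604). The median of oxidative phosphorylation shrank from -0.16 (95% bootstrap interval over members -0.22 to -0.11) to -0.04 (-0.08 to 0.01) with the trend removed, whereas that of antioxidant and iron handling was -0.41 (-0.62 to -0.13), or -0.23 with library totals as scaling, and then -0.36 (-0.59 to -0.02), against a mean of all genes that had fallen as above. Glycolysis and hypoxia genes did not pass (camera adjusted p = 0.0674), with Pkm at 2825 ± 517 and 3311 ± 511 CPM, but were higher as a list with a replicate block (0.00589), with 1 surrogate variable (0.000316) and without vehicle 2, TP-18 1 or TP-18 3 (0.000227 to 0.00902), in a range of 0.000227 to 0.904 over 12 alternatives. Lipid handling (camera adjusted p = 0.8998) and cholesterol biosynthesis (0.708) did not pass. Apoe had 7371 ± 3942 CPM in vehicle and 3013 ± 284 CPM in TP-18 libraries and did not pass.

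Cell cycle genes were higher as a list (camera adjusted p = 2.20e-08). This became adjusted p = 0.568 with an estimated correlation. All 34 members had positive log2 fold changes, with a median of 0.68, and 0 passed over all genes or adjusted over the list alone. Mki67, a marker of proliferating cells, had 229.9 ± 102 CPM in vehicle and 407 ± 145 CPM in TP-18 libraries, and Pcna had 246 ± 33.9 and 263 ± 44.2 CPM. The mean over members of log2 CPM minus the gene's mean was 0.02, -0.30 and -0.69 in vehicle 1, 2 and 3 and 0.46, -0.18 and 0.68 in TP-18 1, 2 and 3. The groups overlapped, and vehicle 1, TP-18 1 and TP-18 3 lay above the other libraries.

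Some lists of markers of other cell types passed with the preset correlation. The fibroblast and pericyte list was higher with a median of 0.75 (camera adjusted p = 4.08e-06). This became adjusted p = 0.388 with an estimated correlation. Of 17 members, 0 passed over all genes, and Col1a1, Col1a2, Lum, Postn, Bgn and Loxl1, 6 in all, were higher when adjusted over the list alone. Col1a2, a chain of type I collagen, had 590.1 ± 159 and 994 ± 111 CPM, and Sparc had 205 ± 67.6 and 306 ± 20.7 CPM. The endothelial list was higher in all 12 members (camera adjusted p = 0.00695). It had an adjusted p = 0.652 with an estimated correlation, and Kdr, a VEGF receptor, was the 1 member higher when adjusted over the list alone, against 0 over all genes. The groups overlapped in the mean over members of log2 CPM minus the gene's mean, at -1.77, 0.96 and -0.73 in vehicle 1, 2 and 3 and 0.69, 0.94 and -0.10 in TP-18 1, 2 and 3, and the estimated correlation between members was 0.787. The most abundant members were Pecam1, at 23.7 ± 21.3 and 40.8 ± 12.1 CPM, and Plvap, at 22.2 ± 20.4 and 31.6 ± 11.4 CPM. Mast cell, basophil and eosinophil markers were higher as a list, with 5 of 6 tested members positive (camera adjusted p = 0.00259). They had an adjusted p = 0.388 with an estimated correlation. Gata2, the most abundant member, was the negative one, at 31.4 ± 11.2 and 24.8 ± 7.76 CPM. Cpa3, Mcpt4, Tpsb2 and Cma1, 4 proteases of mast cells, were higher when adjusted over the list alone, with 0 over all genes, at levels of 1.73 to 7.61 CPM in TP-18 libraries. The endothelial call ended without vehicle 1 or TP-18 2 (camera adjusted p = 0.285 and 0.0664) and the mast cell call without TP-18 2 (0.101). Skin, muscle and adipose markers were lower with a median of -1.34 over 5 genes (camera adjusted p = 0.00745). They had an adjusted p = 0.422 with an estimated correlation, and 0 passed over all genes or adjusted over the list alone. Acta1, the skeletal muscle actin, had 18.2 ± 5.68 and 6.76 ± 6.52 CPM, and Myh4 had 16.4 ± 3.98 and 8.498 ± 10.2 CPM. The groups overlapped in the mean over members of log2 CPM minus the gene's mean, which was 0.36, 0.93 and 0.74 in vehicle 1, 2 and 3, 0.51 in TP-18 1, and -1.14 and -1.41 in TP-18 2 and 3.

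**Figure D2:**
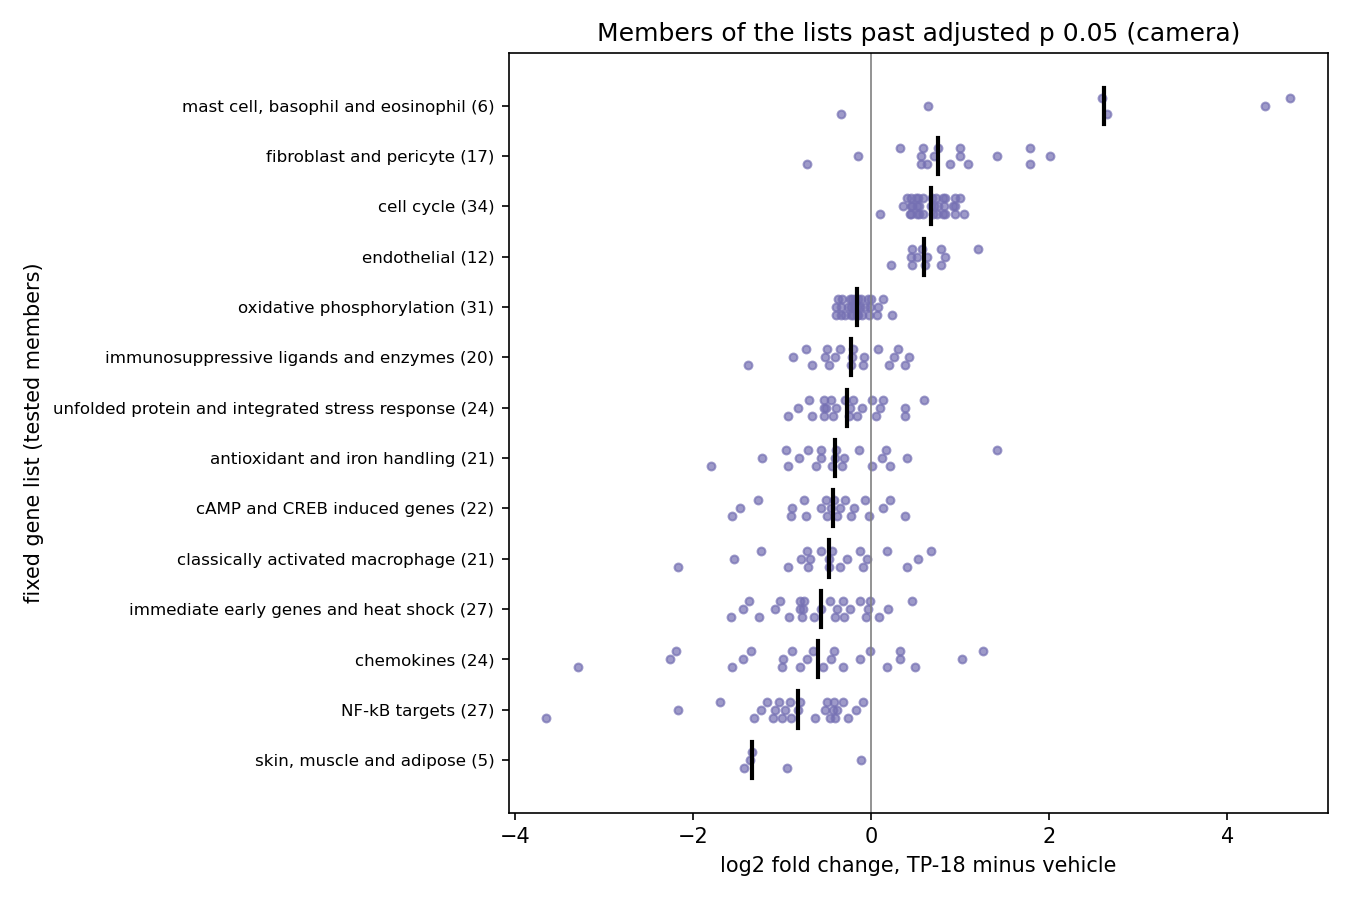
Log2 fold change (TP-18 minus vehicle, x axis) of each tested member, one point per gene, for the 14 lists past adjusted p 0.05 in camera with a preset correlation; black bars are medians, numbers in brackets are tested members, and vertical offsets within a row separate points only. With TMM scaling all 27 NF-kB targets lie left of 0 (25 with library totals), and all 34 cell cycle genes lie right of 0.

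The lists that describe macrophage identity and antigen presentation did not pass. CD206+ or alternatively activated genes had a median of -0.32 (camera adjusted p = 0.0943), with Arg1 at 677 ± 367 and 578 ± 333 CPM. That median was -0.15 with library totals as scaling. Macrophage markers had a camera adjusted p = 0.0752, and Cd14, a lipopolysaccharide co-receptor, was the 1 member lower when adjusted over the list alone, against 0 over all genes, with 1504 ± 264 and 715 ± 95.5 CPM. Interferon lists did not pass, with camera adjusted p = 0.214 for type I and 0.966 for interferon gamma. MHC class I (0.932) and class II (0.8998) presentation, complement (0.309), phagocytosis and lysosome (0.0943), angiogenesis and matrix remodelling (0.768) and the prostaglandin pathway (0.257) did not pass by camera adjusted p. Macrophage markers were lower as a list without vehicle 2 or TP-18 3 (camera adjusted p = 0.000699 and 0.0112), and CD206+ genes without vehicle 1 or TP-18 3 (0.0257 and 0.0125). With all 6 libraries both lists were lower with a replicate block (macrophage 0.0244, CD206+ 0.0262) and with 1 surrogate variable (0.0132 and 0.0317), as were lysosomal genes with the surrogate variable (0.0432), which also made the monocyte list higher (0.0432). Over 12 alternatives the adjusted p ran from 0.000699 to 0.664 for macrophage markers and from 0.0125 to 0.568 for CD206+ genes. Cd74, of the class II pathway, ranged from 66.1 CPM in vehicle 2 to 1646 CPM in vehicle 1. Among other marker lists, monocyte (0.273), neutrophil (0.8998), dendritic cell (0.295), T cell (0.8998), NK cell (0.755) and epithelial (0.8998) lists did not pass by camera adjusted p, and Zbtb46 of the dendritic cell list was lower when adjusted over the list alone. Adjusted over the list alone, 0 members of the other lists in this paragraph passed, as over all genes. The interferon gamma, class I, class II, angiogenesis, T cell and epithelial lists had a median, mean and test that differed in sign. Nos2, Ptger4 and Ptger2 did not pass, with log2 fold changes of 0.67 ± 0.53, 0.38 ± 0.65 and -0.89 ± 0.29 (SE).

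**Figure D3:**
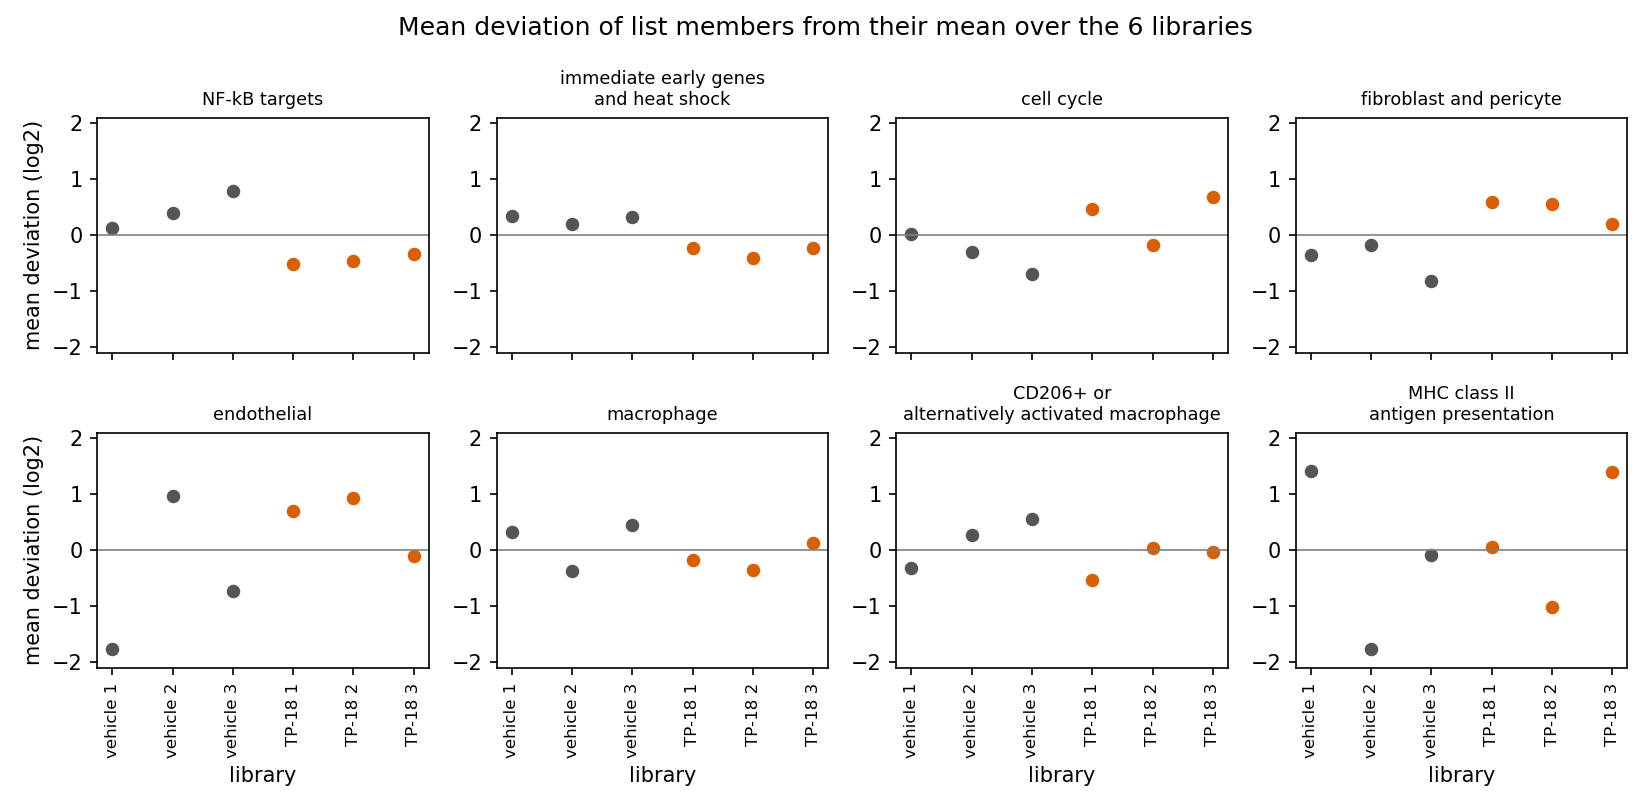
Mean over each list's members of the log2 CPM minus the gene's mean over the 6 libraries (y axis), one point per library (x axis), with vehicle in grey and TP-18 in orange. For NF-kB targets the vehicle libraries lie between 0.13 and 0.79 and the TP-18 libraries between -0.51 and -0.34, while the vehicle libraries span -1.76 to 1.41 for MHC class II presentation.

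Among terms in the deposited annotation, 135 of 2090 GO terms passed with camera's preset correlation, 52 higher and 83 lower. The term extracellular matrix structural constituent conferring tensile strength was higher, with 24 of 27 genes positive (camera adjusted p = 2.26e-06). The term centriole was higher, with 81 of 104 genes positive (camera adjusted p = 0.000646). The term cytosolic ribosome was lower, with 69 of 70 genes negative and a median of -0.44 (camera adjusted p = 4.44e-19). The median of ribosomal protein genes was -0.44 with TMM and -0.27 with library totals, and their share of the counts overlapped between the groups, at 7.63%, 9.49% and 7.09% in vehicle 1, 2 and 3 and 7.20%, 6.40% and 6.45% in TP-18 1, 2 and 3. Cellular response to lipopolysaccharide was lower, with 89 of 125 genes negative (camera adjusted p = 0.000143). Each of these 4 terms had an adjusted p = 0.854 with an estimated correlation. Of 296 KEGG pathways 59 passed, 7 higher and 52 lower, among them the Fanconi anemia pathway (higher, camera adjusted p = 0.000391) and the IL-17 signaling pathway (lower, 3.49e-05). They had adjusted p = 0.717 and 0.652 with an estimated correlation, and 0 GO terms and 0 pathways passed with it. With 6 libraries and this many terms that version could hardly pass any. The term collagen trimer, with an estimated correlation of -0.003, also had an adjusted p = 0.854 in it. The 0 therefore does not decide between correlated genes and low power.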

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

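The correction for GC content and length and the surrogate variable were chosen after seeing the data, the other alternatives before. RLE factors, a CPM filter and leaving out ribosomal protein and haemoglobin genes each gave 3 genes higher and 11 lower, and limma-voom gave 4 and 11. A further limit of at least 2-fold also gave 3 and 11. It could remove none of the 14, whose smallest log2 fold change was -1.08 (Noct). Library totals gave 3 and 1, with the median of all genes shifted by 0.18. DESeq2 gave 163 higher and 342 lower, sample quality weights 4 and 22, limma on log2(FPKM + 1) and on log2(FPKM + 0.1) 1 and 1 each, no filter on low counts 7 and 20, and glmTreat against 1.2-fold 1 and 1. With the trend on GC content and length removed there were 4 and 57, and with 1 surrogate variable 71 and 79. Apart from glmTreat, which asks for a minimum fold, the cause was not tested. The surrogate variable was 0.50, -0.52 and -0.20 in vehicle 1, 2 and 3 and 0.15, -0.42 and 0.49 in TP-18 1, 2 and 3. It was thus positive in vehicle 1, TP-18 1 and TP-18 3 alone, so that fit adjusts for the structure of the samples described below. With a replicate block 3 genes were higher and 0 lower in edgeR, with 1943 at an unadjusted p under 0.05. Of the 14 genes, 2 stayed called with this block, with each fit on FPKM values and with glmTreat, and 4 with library totals. The labels state no pairing, and the numbers showed no clear one: deviations from the group means correlated at 0.16, 0.39 and -0.15 for numbers 1, 2 and 3. Vehicle 1 correlated best with TP-18 3 (0.50), but vehicle 2 with TP-18 2 (0.39). With 3 libraries per group these correlations depend on one another, so they cannot exclude a pairing. Leaving out 1 library gave 0 to 3 genes higher and 0 to 5 lower, from fewer samples: 3 and 5 without vehicle 1, 6 of them among the 14, 1 and 0 without vehicle 2, and 0 without any 1 of the other libraries. The 14 genes had the same sign in every fit run. They were chosen as called and their groups do not overlap, so fits of the same libraries could hardly change a sign. Of 33 fixed lists, 14 passed in the main test, 17 with the replicate block, 10 with the GC and length trend removed and 19 with the surrogate variable. With an estimated correlation 0 passed, as with fry's directional test, whose smallest adjusted p was 0.0552. In fry's mixed test, which gives no direction, 6 passed. The lists gained with the block were macrophage markers, CD206+ and glycolysis genes, and with the surrogate variable these and the lysosomal and monocyte lists. Estimated correlation also left 0 GO terms and 0 KEGG pathways, in a test that could hardly pass any with 6 libraries. With the trend removed the calls of chemokines (median -0.59 before and -0.41 after), oxidative phosphorylation (-0.16 and -0.04), immunosuppressive genes (-0.22 and -0.25) and antioxidant and iron handling (-0.41 and -0.36) ended. The fold of the last 2 changed little, and the mean t of all genes, against which camera sets a list, fell from 0.116 to -0.203. Leaving out 1 library gave 11 to 18 of the 33 lists. The erythrocyte list, which had 5 tested members only without vehicle 3, TP-18 1, TP-18 2 or TP-18 3, passed in these 4 fits as lower. By camera adjusted p, type I interferon genes passed without vehicle 2 (0.00116), complement without vehicle 2 (0.0267), lysosomal genes without TP-18 3 (0.0328), and glycolysis without vehicle 2, TP-18 1 or TP-18 3 (0.000227 to 0.00902). Of 1616 fits of named genes, 123 lost a call, 30 gained one and 0 reversed with a call. A further 80 changed sign without a call in either fit. Only the 14 called genes could lose a call. Each had 18 such fits and passed in 8 (Csf1 among others) to 14 (Iqcn) of them. In simulated data at this depth 23 of 67 genes changed 2-fold were recovered, so most changes of that size or smaller were missed.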

Other observations

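Tests of GC content and length, of macrophage share, of stress during dissociation and of fibroblast share were chosen after the list results were seen, and those of other splits before. The bounds for GC content and length were drawn before the corrected values were seen, and the bounds of the other 3 tests after the values they rest on. A pair of marker lists had too few tested members for a list test with all libraries. The 4 tested haemoglobin and red cell genes all had negative log2 fold changes, with Hbb-bs at 18.8 ± 20.4 CPM in vehicle and 2.72 ± 1.45 CPM in TP-18 libraries, and 42.2 CPM in vehicle 1. Haemoglobin made up 0.0080% of counts in vehicle 1, against 0.0019% and 0.0010% in vehicle 2 and 3, and the groups overlapped for Hba-a1. Of the 4, Hba-a2 and Hbb-bs, 2 genes, were lower when adjusted over the list alone and 0 over all genes in edgeR. Without vehicle 3, TP-18 1, TP-18 2 or TP-18 3 the list had 5 tested members and passed as lower (camera adjusted p = 0.000481 to 0.0131), in fits that all include vehicle 1. The 3 tested B cell genes had positive log2 fold changes and 0 passed, with Cd79b at 1.35 ± 1.49 and 3.91 ± 2.71 CPM. Krt20, an intestinal keratin, was abundant in both groups, at 436 ± 92.1 and 415 ± 152 CPM. The other epithelial and carcinoma markers were far lower, and 7 of 17 were tested. The next most abundant were Lgals4, at 8.36 ± 1.33 and 9.60 ± 2.75 CPM, and Krt18, at 4.11 ± 2.49 and 3.60 ± 1.30 CPM.

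Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 3 genes higher and 11 lower. The split that sets vehicle 1, TP-18 1 and TP-18 3 against the others gave 26 in its larger direction and 51 in all, several times the real count, of which 0 were among the 14, and this points to a structure of the samples. For genes higher and for genes lower, 2 of the 10 splits gave as many. For the fixed lists 3 of the 10 splits gave as many as the real 14, and the highest of the others gave 21. For GO terms 1 of the 10 splits, the real one, gave as many as 135, with 86 the highest of the others. For KEGG pathways 1 of 10 gave as many as 59, with 47 the highest of the others. With 10 splits no share under 0.05 can be had.

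Cx3cr1, Arg1 and Chil3 are 3 of the 51 genes called in the split with vehicle 1, TP-18 1 and TP-18 3 on the same side. Thbs1 and Ptger4 of the cAMP list and Saa3 of the NF-kB list are also among the 51. Cx3cr1, a receptor of monocytes and resident macrophages, had 38.5 CPM in vehicle 1, 1.95 in vehicle 2 and 1.46 in vehicle 3, and 54.9, 1.95 and 64.9 CPM in TP-18 1, 2 and 3. Arg1, the arginase of alternatively activated macrophages, had 262, 960.1 and 808 CPM in the vehicle and 406, 962 and 365 CPM in the TP-18 libraries. Chil3 had 8.91, 758 and 258 CPM in the vehicle and 19.8, 323 and 17.9 CPM in the TP-18 libraries. Cx3cr1, Chil3 and Saa3 were chosen after their values were seen.

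The first pattern was the lower NF-kB target list, the lower combined list of immediate early and heat shock genes, and the lower unfolded protein and integrated stress response list. After the trend on GC content and length was removed, the NF-kB list kept a median of -0.81 (95% bootstrap interval over members -1.16 to -0.58), which argues against that trend as the whole cause. The trend was weak, taking 4.4% of the variance of log2 fold change over genes, which applies to all 3 patterns. The macrophage list's median lay 0.56 above that of the NF-kB list (0.13 to 0.91). This interval takes members as independent, at estimated correlations of 0.30 for macrophage markers and 0.26 for NF-kB targets, and holds no spread between libraries. It therefore does not settle whether a lower share of macrophages was the whole cause. The difference also rests on vehicle 2: without that library it was 0.30 (-0.03 to 0.68), which does not exclude 0. The interval lay above 0 without any 1 of the other libraries, with a replicate block and with 1 surrogate variable. Macrophage markers were lower as a list without vehicle 2 or TP-18 3, with the block (camera adjusted p = 0.0244) and with the surrogate variable (0.0132), so a lower share may account for part of the pattern. Stress during dissociation that differed between the groups stays open: 12 handling-induced genes had a median of -0.27 (-0.69 to 0.04), between the bounds for and against it, which were drawn afterwards. The list's 8 heat shock genes (median -1.17) lay well below the 10 immediate early genes among these 12 (-0.15). The list's other members were not summarised apart. An effect of TP-18 on NF-kB signalling may also account for the pattern and was not tested apart from these.

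The second pattern was the higher fibroblast and pericyte list. Its median was 0.75 before and 0.59 after the trend on GC content and length was removed (0.48 to 1.05), which argues against it as the whole cause. A higher share of fibroblasts and pericytes in the TP-18 libraries stays open. Among 11 abundant markers 2, Col1a1 (1.79) and Col6a1 (-0.15), had a 95% interval that excluded the median log2 fold change of the list's other members, between bounds that were drawn afterwards, and the intervals of 7 were narrow enough to show a marker that did not rise. Col6a3, another chain of collagen VI that is not on the list, rose by 1.96. The most abundant markers were Col1a2, at 590.1 and 994 CPM, Sparc, at 205 and 306 CPM, and Col6a1, at 198 and 178 CPM. Either sort described in the labels should remove such cells, but the sample characteristics name the CT26 line itself. Of the 17 tested members 0 are on another fixed list. Expression of these genes by the sorted cells or by CT26 cells was not tested.

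The third pattern was the higher cell cycle list. Its median was 0.68 before and 0.63 after the trend on GC content and length was removed (0.55 to 0.72), which argues against the trend as the whole cause. The estimated correlation between its members was 0.83, while this interval takes them as independent. The mean over members of log2 CPM minus the gene's mean was higher in vehicle 1 (0.02), TP-18 1 (0.46) and TP-18 3 (0.68) than in vehicle 2 (-0.30), vehicle 3 (-0.69) and TP-18 2 (-0.18), which is the split that called 51 genes. On both sides of that split the TP-18 libraries lay above the vehicle libraries. A difference in the share of cycling cells that follows the structure of the samples may therefore underlie part of the pattern. With 1 surrogate variable, whose sign followed that split, the list still passed by camera with the preset correlation. It passed in 10 of 12 alternatives, failing with an estimated correlation and with fry's directional test. An effect of TP-18 stays among the open explanations.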
